A study of Populus alba x Populus glandulosa with 6 samples.

How the data were processed

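RNA of poplar leaves was measured on 6 two-colour Agilent oligonucleotide arrays with 59253 spots each, 2 arrays for each of 3 groups (control, drought and salt). Per the labels, total RNA was extracted with Trizol, and the labelled RNA of a leaf sample (Cy5) was hybridised together with a reference pooled from 18 samples (Cy3). All arrays have this dye orientation, so no dye swap cancels a dye effect within a group, although a constant dye effect cancels between groups. The reference channel correlated at 0.996 to 0.998 between arrays and the leaf channel at 0.889 to 0.974, as the labelled dyes require. The group and the replicate number (2 or 4) of a sample were taken from its title. The leaf channel of the drought samples is described as Day-treated where the title says Dry, and the title was followed.

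Per the file headers, the arrays were read with Agilent Feature Extraction 11.0.1.1, whereas the submitters' processing notes list version 9.3.2.1, and the array design refers to genome build Poptr 1.0. The intensity values used here are the median pixel brightness of each spot and of its local background in both channels, deposited per array without normalization. The files hold no mean spot signals, for which the plan had been written, so median signals took their place. The authors' files also hold intensity values after background subtraction and dye normalization by the scanner software, and the log10 ratio of these processed values. That log10 ratio lay within 0.01 of the ratio of the processed signals for 100% of the spots on control 4 and for 81.2% to 85.0% on the others, where the remaining spots read 0. The deposited value table of the series holds log2 ratios of sample over reference. Set against the scanner log ratios after centring each transcript, its columns correlated at 0.973 to 0.999 with slopes near 1, which settles scale and direction. A further value had been subtracted from each transcript, which was neither the mean nor the median of these arrays, and where it came from stays unknown. The column medians of the table were 0.107 for control 2, -0.00289 for control 4, -0.0561 for drought 2, 0.0177 for drought 4, -0.0526 for salt 2 and -0.00896 for salt 4. How the authors filtered or tested these values is not given in the sources used here.

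From the median signals, background was corrected with normexp (offset 50), log2 ratios of Cy5 over Cy3 were normalized by loess within each array with control spots at weight 0, and no scaling was applied between arrays, with limma 3.58.1 in R 4.3.3. Control spots and 48 values marked as outliers by the scanner software were left out afterwards, and no spot was saturated. A transcript was kept where the leaf channel was well above background on both arrays of at least 1 group, which left 41806 of 57934. Between 67.5% and 73.8% of the transcripts were well above background on an array. Each identifier has 1 probe, and 44717 identifiers are of the PACid kind and 13217 are probe numbers. The files do not pair either kind with gene names, and no annotation was used here, so the 34 gene lists fixed in advance were matched to no transcript and no test of gene lists was run. For the same reason at most 2 identifiers each way are named in a comparison, by a rule fixed in advance: those with the largest difference among transcripts past the threshold, or, where none passed, those with the smallest unadjusted p.

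All 6 arrays of the 3 groups entered a limma fit (lmFit and eBayes) on the log2 ratios with a term for each group and no other, and the contrasts were drought minus control, salt minus control and drought minus salt. A transcript was called at a Benjamini-Hochberg adjusted p under 0.05 over all 41806 transcripts, two-sided. The fit has 3 residual degrees of freedom, to which the moderation across transcripts adds 2.96. With groups of 2 arrays no outlier test and no regrouping of the samples was made. Slides were told apart by the array headers. Slide 1 held control 2 and salt 2, slide 2 held control 4 and drought 2, and slide 3 held drought 4 and salt 4, each read in 1 scan, so slide and group can be separated in part. A fit with slide as a fixed block, with 1 residual degree of freedom and 6.38 from moderation, is reported beside the fit without it, as are differences within the slide that holds both groups.

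The test was checked on simulated data for the comparison of drought with control, over 41771 transcripts, 10 repeats and noise that was independent, common to a slide or common to a replicate number. With no changed transcript the fit without a block called 0 to 0.1 transcripts on average and the fit with slide as a block 0.5 to 2.4. With 200 changed transcripts and independent noise, the fit without a block recovered 2.4% of log2 changes of 1, 74.6% of 2, 93.8% of 3 and 97% of 4, and the false share of its calls was 7.34%. With noise common to a replicate number the same fit recovered 0.2%, 30.2%, 79.2% and 91.2% of these sizes. With 4000 changed transcripts and slide effects, it recovered 51.4% of changes of 1 and 94.6% of 2 with a false share of 0.528%. The fit with slide as a block then recovered 90.0% of changes of 1 and 99.5% of 2 with a false share of 7.22%. Over the simulated settings with changed transcripts the false share of the calls with slide as a block was 7.22% to 19.8%, above the nominal level, so its counts are less strictly controlled.

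Alternatives were no background correction, normexp with offset 16, the scanner log ratio, the deposited value table, median centring, Aquantile and scale normalization, the leaf channel alone after quantile normalization, no filter on dim transcripts or a filter on all arrays and both channels, a variance trend on brightness or on the mean log ratio, robust variance, array weights, only the groups compared, the replicate number or the slide as a block, and each array left out in turn. Shared controls were simulated 50 times by drawing unchanged values for 6 arrays with the spread of each transcript, and again 50 times for each fit, from which the transcripts with the smallest p were taken as lists of the observed lengths. The lists read against 1 control array each were added after seeing the data. Covariances and correlations are across transcripts. Figures were drawn with matplotlib.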

Results

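Transcript levels were measured in leaves of hybrid poplar (Populus alba × P. glandulosa) under water shortage and under salt. The plants had grown in soil for 6 weeks and stood about 15 cm tall. Drought was a gradual drying without watering for 9 days, and salt was 150 mM NaCl for 24 hours. Control leaves were taken just before the stresses began, so the drought and salt leaves also differed from the control leaves in the time of harvest. Each of 3 groups had 2 arrays, which carry the replicate numbers 2 and 4 of the labels, and each array set a leaf sample in Cy5 against a reference in Cy3 that was pooled from the RNA of 18 samples. Harvests are given as 3 plants, and nothing says whether replicates 2 and 4 came from separate plants, so the p-values measure the spread between these samples, which may be technical.

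The array carried 57934 transcripts with 1 probe each, of which 41806 were well above background in the leaf channel on both arrays of at least 1 group. In all 3 groups 36765 transcripts were measured this way. The median leaf signal was 251 and 236 on the control arrays, 212.5 and 223 on the drought arrays, and higher, at 410.5 and 382.5, on the salt arrays. Signal over background in the leaf channel ran from 3.86 on drought 2 to 7.46 on salt 2. The number of arrays, 2 in a group, limits the precision of every value.

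The drought arrays lay apart from the controls on the main axis of variation, while the salt arrays did not both do so. Across transcripts, which are not independent replicates, the log2 ratios of the 2 drought arrays correlated at r = 0.82 and those of the 2 salt arrays at r = 0.59. The 2 control arrays correlated at r = -0.22, lower than control 2 with salt 2 (0.27, on the same slide), control 4 with salt 4 (0.36) or control 4 with drought 4 (0.35). The log2 ratios varied less on the control arrays (SD 0.408 and 0.345) than on the other arrays (0.525 to 0.887). In the leaf channel the control arrays correlated at 0.964, the salt arrays at 0.960, the drought arrays at 0.974 and control 2 with salt 2 at 0.966. The main axis held 54.8% of the variance and ran from control 2 to drought 4, with salt 2 beside control 4, and the next axis, with 18.7%, set both salt arrays apart. The main axis also set slide 1, at -108.7 and -46.7, apart from slide 3, at 101.3 and 40.3. The controls lay on slides 1 and 2 and the drought arrays on slides 2 and 3, so drought and slide are not fully separated on it.

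**Figure D1:**
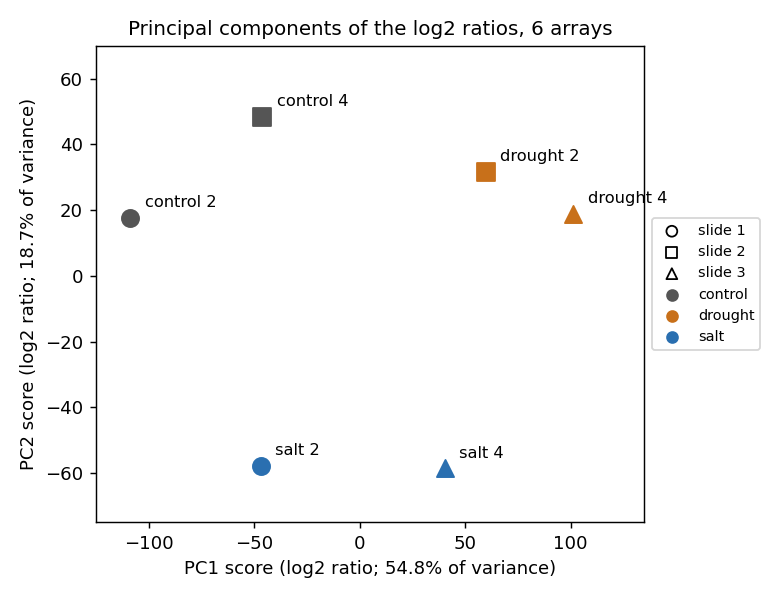
Scores of the 6 arrays on the leading principal components of the log2 ratios, coloured by group and shaped by slide. On the horizontal axis the controls sit at -108.7 and -46.1, the drought arrays at 59.9 and 101.3 and the salt arrays at -46.7 and 40.3, and on the vertical axis the salt arrays sit at -57.9 and -58.6.

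The comparison of drought with control asked which leaf transcripts respond to water shortage. In drought 427 transcripts rose and 727 fell, and each of these 1154 differed by at least 2-fold. The median transcript that rose was 4.29-fold higher, and the median transcript that fell was 3.98-fold lower. The highest changes were mostly rises: 52 transcripts rose at least 16-fold and 15 fell at least 16-fold. The files do not pair the identifiers with gene names, so transcripts appear under their array identifiers.

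The largest rise was that of PACid:18220750, by 8.55 on the log2 scale (SE 0.27, limma adjusted p = 0.000672). Its log2 ratio to the reference was -1.19 ± 0.19 in control and 7.36 ± 0.43 in drought (mean ± SD, n = 2). PACid:18220897 rose by 8.32 (SE 0.24, limma adjusted p = 0.000672), from -0.62 ± 0.34 to 7.70 ± 0.23 (SD, n = 2). The transcript CUST_10420_PI428237995 fell by 8.18 (SE 1.32, limma adjusted p = 0.0425) to -8.72 ± 0.01 (SD, n = 2). It was well above background on both control arrays and on 1 of the 2 drought arrays, so the size of its fall depends on the background step, and it was -8.89 with the smaller offset and -9.90 by the scanner log ratio. Its control arrays were far apart, at 1.21 and -2.28. With slide as a block its difference was -6.63, and without control 2 or control 4 it was -6.44 or -9.93. PACid:18206817 fell by 6.93 (SE 1.0, limma adjusted p = 0.0348), from 0.03 ± 1.43 to -6.90 ± 0.07 (SD, n = 2). Its control arrays read 1.04 and -0.99, and with slide as a block its difference was -5.67. The plot of named transcripts shows each array.

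**Figure D2:**
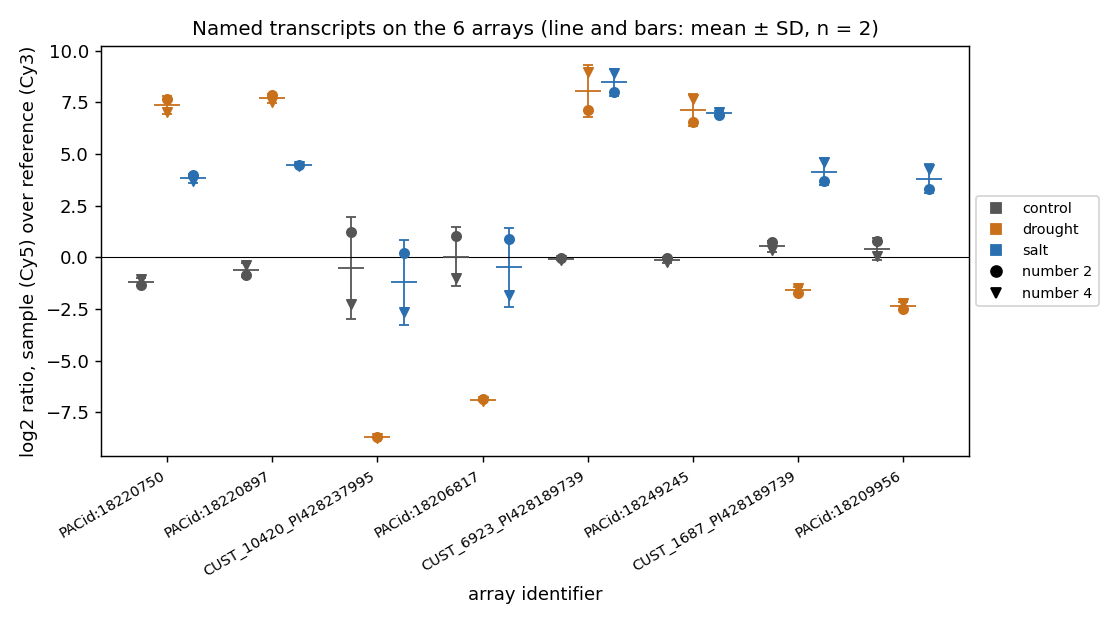
Log2 ratio of leaf sample over pooled reference for the 8 named transcripts, with a point for each array, a line for the group mean and bars for the SD (n = 2). The drought points of PACid:18220750 lie at 7.66 and 7.06 and its control points at -1.32 and -1.06, while the control points of CUST_10420_PI428237995 lie at 1.21 and -2.28.

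Transcripts that fell in drought were spread over the brightness range except at its low end. Among the dimmest of 5 equal classes, 49 transcripts rose and 12 fell, and among the brightest class 138 rose and 211 fell. Of 370 transcripts well above background on both drought arrays and on neither control array, 29 rose, and 80 rose with slide as a block. Of 918 transcripts with the opposite pattern, 26 fell, and 129 fell with slide as a block. Transcripts with a PACid identifier fell less often than the other probes, at 1.64% of 31921 against 2.05% of 9885 (Fisher's exact test, two-sided, p = 0.00719, Benjamini-Hochberg p = 0.0288 over 8 tests). With slide as a block that difference did not pass (Fisher's exact test, Benjamini-Hochberg p = 0.079). Fisher's test takes transcripts as independent, which they are not, and brightness was not matched between the kinds of identifier.

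Each of the 3 slides held arrays of 2 groups. The controls lay on slides 1 and 2 and the drought arrays on slides 2 and 3. The drought difference without the block therefore also holds part of any difference between slide 3 and slide 1. With slide as a fixed block, 2066 transcripts rose and 3379 fell in drought, and all 1154 transcripts above were among them with the same direction. Within slide 2, which held drought 2 and control 4, all 1154 also differed in that direction, although these arrays enter the fit too. Without control 2, control 4, drought 2 or drought 4 the count was 8, 7, 9 and 8, all of them rises, so none of the 727 falls passed in a fit in which a group has 1 array, assumed to vary like the other groups. The 1154 transcripts kept their direction, and PACid:18206817, for example, lay between -7.94 and -5.92 in these fits.

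The comparison of salt with control asked the same of salt. After 24 hours 18 transcripts rose and 0 fell in the limma fit, whereas 3308 were higher and 2381 lower at an unadjusted p under 0.05. The unadjusted counts are not calls, since many of 41806 transcripts would pass that limit with no change. All 18 rose at least 4-fold and 12 at least 16-fold, with a median of 26.1-fold. CUST_6923_PI428189739 rose by 8.54 on the log2 scale (SE 0.61, limma adjusted p = 0.0287), from -0.07 ± 0.05 in control to 8.47 ± 0.64 in salt (SD, n = 2). PACid:18249245 rose by 7.10 (SE 0.37, limma adjusted p = 0.0101), from -0.13 ± 0.16 to 6.97 ± 0.10 (SD, n = 2). From the leaf channel alone, without the reference, these differences were larger, at 10.64 and 10.59, and with slide as a block they were 7.78 and 6.67. The reference readings of these spots were thus also higher on the salt arrays than on the control arrays, although each array carried the pooled reference. The sizes of these rises are uncertain for that reason, and its cause was not tested. Both transcripts also stood high in drought, with means of 8.05 ± 1.28 and 7.12 ± 0.78 (SD, n = 2).

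More transcripts were measurable in salt than in control. Well above background on both salt arrays and on neither control array were 1021 transcripts, and 50 showed the opposite pattern. None of these 1021 passed the test in the fit without slide, where 0 rose, and 54 rose with slide as a block. The leaf signal was brighter on the salt arrays, as given above.

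With slide as a fixed block, 1194 transcripts rose and 877 fell in salt, so that rises made up 57.7% of the calls in place of 100%, and all 18 transcripts above were among those that rose. Within slide 1, which held salt 2 and control 2, all 18 were higher in salt. The count fell to 0 without control 2, without control 4 or without salt 4, was 9 without either drought array, and was 30 without salt 2.

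**Figure D3:**
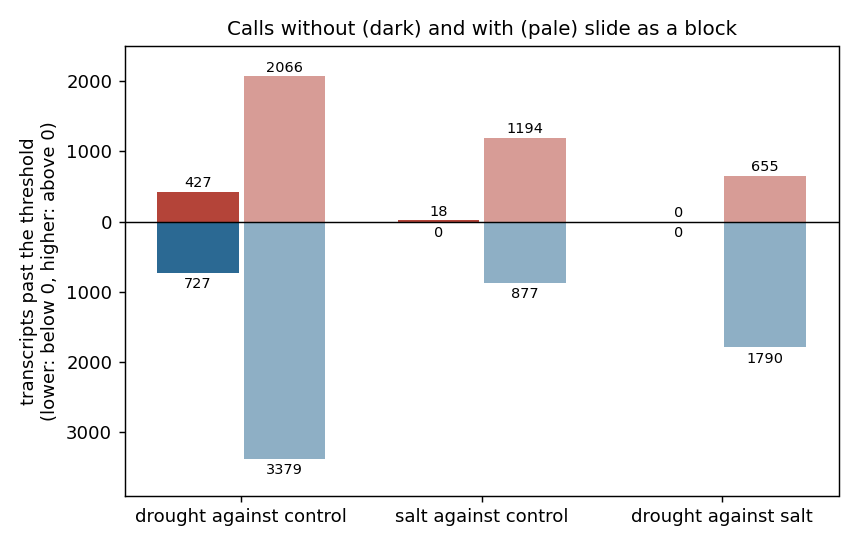
Numbers of transcripts past the threshold that were higher (bars above 0) and lower (bars below 0) in each comparison, without slide in the model (dark) and with slide as a fixed block (pale). In drought against control the bars reach 427 and 727 without the block and 2066 and 3379 with it.

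The comparison of drought with salt asked how the stresses differ from each other. Drought lasted 9 days and salt 24 hours, so the length of the stress differed too, and the time of harvest may also differ. No transcript passed in the limma fit without slide (0 calls, smallest adjusted p = 0.0883), while 1929 were higher and 3378 lower in drought at an unadjusted p under 0.05. As for salt, many transcripts would pass the unadjusted limit with no change. The transcripts with the smallest unadjusted p each way are given as values. PACid:18220897 differed by 3.24 (SE 0.24) and PACid:18220750 by 3.54 (SE 0.27) on the log2 scale, drought minus salt, with salt means of 4.46 ± 0.04 and 3.82 ± 0.20 (SD, n = 2). CUST_1687_PI428189739 differed by -5.73 (SE 0.35) and PACid:18209956 by -6.15 (SE 0.41). In control the latter were at 0.55 ± 0.27 and 0.42 ± 0.53, in drought at -1.59 ± 0.18 and -2.35 ± 0.19, and in salt at 4.14 ± 0.66 and 3.80 ± 0.70 (SD, n = 2).

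When slide was a fixed block, 655 transcripts were higher and 1790 lower in drought than in salt. Under that block PACid:18220897 and PACid:18220750 were higher in drought (limma adjusted p = 0.00155 and 0.00111). CUST_1687_PI428189739 and PACid:18209956 were lower in drought (limma adjusted p = 0.000579 and 0.000829). Within slide 3, which held drought 4 and salt 4, 980 transcripts were at least 2-fold higher in drought and 2178 at least 2-fold lower, with no test.

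The overlap of the responses was compared last. Both stresses were set against the same control arrays, which by itself pushes the differences the same way, so each count stands beside that of lists of the same lengths from 50 simulations of unchanged groups against shared controls. These simulations drew each array independently. Variation common to a slide or a replicate number is therefore not allowed for in the simulated counts. Every simulated list holds unchanged transcripts picked for the smallest p. The 18 observed salt calls, by contrast, had a median rise of 26.1-fold. The simulated counts thus do not say how many of the observed overlaps come from the shared controls. Of the 18 transcripts that rose in salt, 16 also rose in drought, where the simulated lists shared 9.76 on average and 14 at most, and independent lists would share 0.184. Of the 427 transcripts that rose in drought, 400 had a higher mean in salt than in control (simulated 378.1, at most 390), with a median log2 difference of 1.11 in salt and 2.1 in drought. Of the 727 that fell in drought, 702 had a lower mean in salt (simulated 635.8, at most 652), with medians of -0.99 and -1.99. When slide was a block, 615 transcripts rose under both stresses (simulated 368.2, 59.0 for independent lists) and 679 fell under both (simulated 384.4, 70.9 for independent lists). In opposite directions, 33 fell in drought and rose in salt (simulated 10.0, 96.5 for independent lists), and 4 rose in drought and fell in salt (simulated 5.2, 43.3 for independent lists).

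Across the 41806 transcripts the drought and salt differences correlated at r = 0.67, beside a simulated 0.50 from the shared controls alone. The covariance was 0.312, beside a simulated 0.0569, a difference of 0.255. The spread between the 2 control arrays gives a larger shared part of 0.087, which leaves 0.225. With 2 controls no split keeps 2 arrays on each side, so part of the excess may come from the shared controls. Of the 427 largest rises and 727 largest falls of drought against control 2 alone, 81.3% and 54.2% had the same direction in salt against control 4 (52.9% and 47.1% of all transcripts were higher and lower there). With the controls exchanged these shares were 93.2% and 86.2% (51.5% and 48.5% of all transcripts). In both readings drought 4 and salt 4 still shared slide 3.

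**Figure D4:**
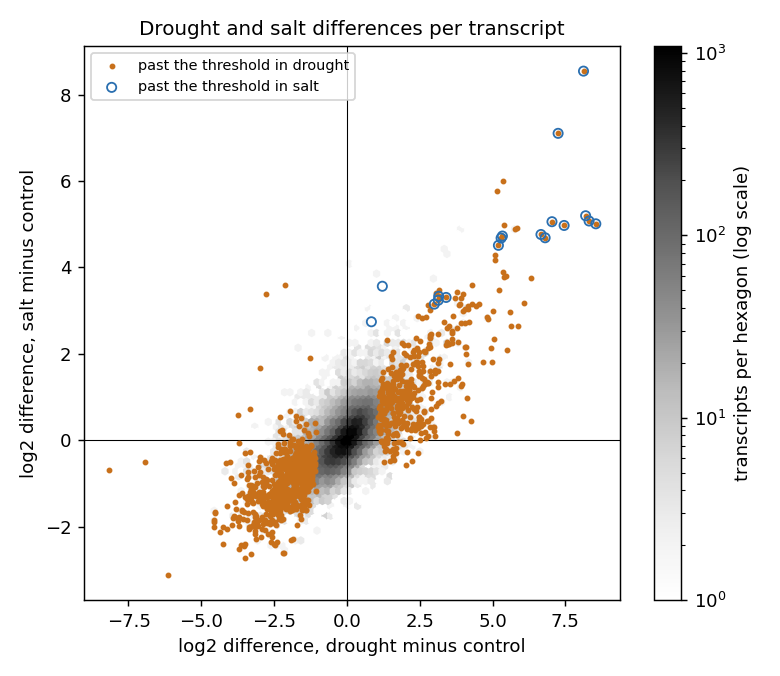
Log2 difference from control in drought (horizontal) and in salt (vertical) for each transcript, in grey hexagons shaded by number on a log scale, with the 1154 transcripts past the threshold in drought as orange points and the 18 past it in salt as blue rings. Of the 18 ringed transcripts, 16 are also orange, and 400 of the 427 orange points right of 0 lie above 0 in salt.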

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

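The alternatives compared here were chosen before the data were examined, except for the form of the variance trend. A trend on the mean log ratio was run first, and it gave 0 calls for drought, 0 for salt, 3 between the stresses (all at least 2-fold) and 0 shared. The trend on brightness took its place after these counts were seen, and it gave 1163 drought calls and 23 salt calls. Of the 24 tested alternatives, 11 leave the log2 differences of a comparison as they are and change at most the test or the set of transcripts. Among these 11, Aquantile normalization gave the main counts and adjusted p again, so it is no separate check. The filter on all arrays and both channels held 1018 of the 1154 drought calls. Under the other 13 all 1154 drought calls and all 18 salt calls kept their direction. These calls had passed the threshold in the same arrays, so a reversal was unlikely from the start. The side of the threshold was less stable, and unless stated the cause was not tested. Both rises named for drought passed in 23 of 24 tested alternatives, all but the trend on the mean log ratio (limma adjusted p 0.371 and 0.772 there). CUST_10420_PI428237995 passed in 16 of 23 (adjusted p 5.73e-05 to 0.855) and PACid:18206817 in 18 of 24 (7.85e-05 to 0.253). For salt CUST_6923_PI428189739 passed in 17 (0.000178 to 0.996) and PACid:18249245 in 20 of 24 (0.000178 to 0.982). The differences of these 4 ranged from -9.93 to -6.33, -7.94 to -5.66, 7.41 to 10.64 and 6.67 to 10.59. Of the transcripts given for drought against salt, each passed in 4 to 6 of 24.

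Scale normalization between arrays gave 539 drought calls, all at least 2-fold, 81 salt calls, 1 call between the stresses and 56 shared calls. Median centring gave 42 salt calls, 20 between the stresses (3 higher and 17 lower in drought) and 27 shared; it moved the median of all differences to 0.13 for salt minus control and -0.20 for drought minus salt on the log2 scale. Salt calls were 28 without background correction, 30 with the smaller offset (25 shared) and 9 with only the groups compared (8 shared), a setting that gave 1455 drought calls. Shared calls were 10 without a filter on dim transcripts and 10 with array weights. The scanner log ratio gave 1 call between the stresses and a covariance of 0.56, and the deposited values gave 0.556. Drought against control 2 with salt against control 4 gave a covariance of 0.166 with no array in common, and the reverse gave 0.284. The arrays still shared slides, and independent slide effects would lower the former covariance and raise the latter.

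With slide as a fixed block the counts were 5445 for drought (4234 at least 2-fold), 2071 for salt (1997), 2445 between the stresses (2300) and 1294 shared. As a random block they were 6945 (3941), 3312 (1796), 2424 (1677) and 1930. The replicate numbers 2 and 4 are shared by the groups, but nothing says what they mark, and with 2 numbers a pairing cannot be settled from the data. With the replicate block the counts were 6652 (5010), 1301 (1284), 1670 (1616) and 956 shared, and the deviations of same-numbered samples correlated at 0.264 to 0.582 between groups. In simulations with noise common to a number, the false share was 5.18% to 7.52% with the replicate block and 11% to 19.8% with slide as a block.

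Leaving out each array in turn gave 7 to 1455 drought calls, 0 to 30 salt calls, 0 to 0 between the stresses, 0 to 23 shared and a covariance of 0.187 (without salt 4) to 0.501 (without control 4). The same ranges held for calls of at least 2-fold. A lone array was assumed to vary like the other groups. The counts moved both ways: leaving out either salt array gave 1455 drought calls and leaving out salt 2 gave 30 salt calls. The gene-list alternatives were not run because no list could be matched, and the alternatives on several probes of a gene had nothing to act on, since 0 identifiers have several probes. Signal over background, 3.86 to 7.46 in the leaf channel, limits what can be measured in dim transcripts.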

Other observations

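The tests of consecutive identifiers were set before their results were seen, and the tests of arrays with the same number and of the pooled reference were chosen only after the result was seen.

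Among the transcripts well above background on neither control array, 53 were so on both drought arrays and neither salt array, 435 on both salt arrays and neither drought array, and 233 on all arrays of both stresses. The leaf channel was brighter on the salt arrays (median signal 410.5 and 382.5) than on the drought arrays (212.5 and 223), which bears on these counts. Transcripts that rose in salt with slide as a block were rarer among PACid identifiers, at 2.68% of 31921, than among the other probes, at 3.42% of 9885 (Fisher's exact test, two-sided, Benjamini-Hochberg p = 0.0013 over 8 tests). Without the block 10 and 8 transcripts rose, which did not pass (Fisher's exact test, Benjamini-Hochberg p = 0.0999). As for drought, the test takes transcripts as independent and brightness was not matched. Of the 2066 transcripts that rose in drought with slide as a block, 494 also passed as different from salt, as did 1114 of the 3379 that fell.

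In all 3 groups the array numbered 4 differed from the array numbered 2 in like ways across transcripts. The control and drought shifts share slide 2 with opposite signs, so independent slide effects would make them correlate below 0. They correlated at 0.264, which argues against independent slide effects as the whole cause. Control with salt (0.582) and drought with salt (0.528) share a slide with the same sign and correlated higher. Slide effects thus remain a candidate for part of the likeness. Slide effects graded from slide 1 to slide 3 would make all 3 shifts correlate above 0, so slide is not excluded. For background correction and dye normalization, the lowest of the 3 correlations in the brightest class and in the scanner log ratio was 0.25. Both settings are themselves background-corrected and dye-normalized, so an effect common to these steps is not excluded by them. The leaf channel alone, background-corrected and quantile-normalized without dye normalization, gave correlations of 0.244 to 0.574, so dye normalization is not needed for the likeness. Whether the samples numbered 4 lay further along the drought response cannot be told apart from slide: the salt, drought and control shifts correlated at 0.511, 0.241 and 0.336 with drought minus control, salt minus control and drought minus salt, which hold slide effects by design, and the control shift plus the drought shift minus the salt shift, in which slide effects cancel but so would a further response of salt 4, correlated with drought minus control at 0.029. What the samples of a number share stays open, since handling common to a number was not tested, and the reference channel, a pool on every array, gave shift correlations of -0.0151 for control with drought, 0.0714 for drought with salt and 0.307 for control with salt.

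Transcripts with consecutive PACid numbers had like drought differences, with r = 0.147 over 22685 pairs, and 75 pairs were both called in the same direction, against 8.96 on average and 17 at most when identifiers were shuffled within brightness classes, and 8 pairs were called in opposite directions. Closeness on the array is argued against by r = 0.139 over pairs at least 50 spots apart in row or column, and like brightness by a highest r of 0.0167 in 100 such shuffles. Probes that see the same transcripts are a candidate explanation, since r was 0.0352 where the reference signals of a pair differed by over 4-fold and 0.351 where they lay within 2-fold. The shift between the salt arrays also correlated between neighbours, at 0.137, so shared variation between samples cannot be told apart from the response, because it too follows transcripts. The files do not say whether such pairs are forms of a gene, so the number of genes behind the 1154 calls may be lower.

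Some transcripts exceeded the pooled reference by more than 18-fold on both arrays of a stress group, 40 in drought, 15 in salt and 6 in both, against 0 in control; by the scanner log ratio these were 113 in drought, 47 in salt and 5 in control. If the reference were an equal pool of 18 samples that held both arrays of a group, no transcript could exceed it by more than 9-fold on both on a linear scale, yet 79 did in drought, and 213 by the scanner log ratio. Of the transcripts above 18-fold, 91.8% had a reference well above background on both stress arrays, which argues against a reference lost in background there. The control arrays were not read for this, so a reference nearer to background on other arrays is not excluded. For PACid:18249245 the salt difference was 7.10 by the ratio and 10.59 from the leaf channel alone, so its reference reading was not constant between arrays. Unequal shares in the pool, a pool of other samples and a response of the scanner that is not linear stay open, and no biological explanation was tested.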
